A study of Homo sapiens with 8 samples.

How the data were processed

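The study measured enriched mRNA by RNA sequencing in primary HUVECs at day 4 after siRNA transfection, in 4 siCtrl and 4 siKLF2 libraries. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures or donors, so p-values measure the spread between these libraries, which may be technical. No pair of libraries was a duplicate: their reads differed by a chi-square of 9.9 to 46.6 per gene within groups.

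Per the submitters' processing notes, reads were handled with bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.1 and DESeq2 1.24 on the genome build GRCh38; the annotation release and whether counting used the strand are not given in the sources used here. Reads from a gene and an overlapping or antisense partner, and reads shared between near-identical copies, therefore cannot be told apart. The deposited values per library are a signal in units of reads divided by 1 size factor per library, as the authors' DESeq2 columns beside them show, and not raw counts. This was read from the values: each is a whole multiple of what 1 read is worth in its library, within a tolerance of 1e-06, for all of the 259368 values but 1. The exception is SMAD5 in siCtrl 3, and SMAD5 was left out of tests on whole reads. The deposited table also holds the authors' mean signal, log2 fold change and its standard error, test score (Wald statistic) and p-value with adjusted p-value, per the file headers. In 1 of 32421 rows (SMAD5) the deposited score is not the log2 fold change divided by its standard error. The authors' mean does not equal that of the 8 libraries (ratio up to 1.5), so their fit presumably held other libraries, which are not analysed here. The authors' deposited table has 3787 genes higher and 3577 lower among 19839 with an adjusted p-value.

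Main test. Genes with a normalised value of at least 10 in at least 4 libraries were kept (14678 of 32421). Values were analysed as log2(value + 1) with limma 3.58.1 (empirical Bayes with a mean-variance trend, robust), group as the only term, and Benjamini-Hochberg adjustment over all tested genes, threshold 0.05; fold changes on this scale understate the change of genes with few reads. The plan fixed before the data were examined assumed raw counts and named edgeR's quasi-likelihood test. That test, run on the recovered whole reads with edgeR 4.0.16, is therefore an added alternative: it tested 14728 genes and called 3519 higher and 3410 lower at a biological coefficient of variation of 0.139. Also tried were edgeR with RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, other filters, the replicate number as a block, each library left out, stricter thresholds, estimated correlations and fry for lists. Pseudocounts of 0.5 and 5, TMM factors, removal of the trend on GC content and length, that removal together with an estimated correlation, and omission of both libraries with the steepest GC slope were chosen after seeing the data.

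Lists. 30 lists with 434 genes were fixed before the data were examined, 417 of the genes were found in the table (older symbols matched) and 378 tested. The lists with at least 3 tested members (28) were tested with camera (limma, two-sided, preset correlation 0.01) and adjusted over the 28; leukocyte and epithelial markers, with 2 tested members each, were not. The 30 lists were genes induced and repressed by KLF2, the KLF family, the MEKK3 to MEF2 axis, BMP modulators, BMP ligands, receptors and SMADs, SMAD1/5 targets, TGF-beta and mesenchymal, arterial and Notch, venous and capillary, pan-endothelial, junction and barrier, NF-kB, interferon-stimulated, coagulation, vasoactive, angiogenic and tip cell, cell cycle, cholesterol, glycolysis, YAP/TAZ, stress response, p53, matrix, and markers of smooth muscle, fibroblasts, leukocytes, lymphatic and epithelial cells, and mitochondrial genes. Several genes are in more than 1 list, for example KDR and CXCR4. Named genes followed a rule fixed beforehand: KLF2 and BMPER, the 12 largest rises and 12 largest falls among protein-coding genes with adjusted p below 0.05, mean CPM of at least 5 and no overlap between groups, up to 4 members of each list with the smallest adjusted p and its most abundant member not past the test, and any tested BMP modulator or SMAD1/5 target. SMAD5 was singled out after its values were seen.

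GC content and length came from GENCODE 29 transcripts (GRCh38), with 14635 tested genes matched (99.7%). For each library the deviation from the gene's mean over the 8 libraries was smoothed on GC content, then on log2 length (lowess, span 0.3), and subtracted. Group differences in library measures were tested with exact permutation tests, whose smallest p is 0.0286. The tests were run on simulated reads for 14396 genes, with the mean levels of siCtrl and the depths of all 8 libraries. Of 200 genes changed, 81.4% were recovered at a log2 size of 1 and 100% at 2. Unchanged genes made up 5.32% of calls. A shifted list was called and 0 of 29 unshifted lists were. Simulated genes varied independently, so this does not test camera's preset correlation where genes vary together. A GC slope added equally to every siKLF2 library gave 3256 false calls, which the correction reduced to 11. In the data, slopes differed between libraries of a group and 47.2% of genes were called. The simulated rates of recovery, false calls and correction therefore need not hold for the data. Computation used R 4.3.3 and Python 3.11.15.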

Results

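Human umbilical vein endothelial cells (HUVECs), primary cells from the inner lining of the umbilical vein, received either a control siRNA (siCtrl) or an siRNA against KLF2 (siKLF2), and their enriched mRNA was sequenced at day 4. KLF2 is a zinc-finger transcription factor that laminar blood flow induces in endothelium. Each group held 4 libraries, with 18192641 (siCtrl 3) to 23744291 (siKLF2 4) reads assigned to genes per library. The design gives 1 comparison, siKLF2 against siCtrl. It asks which transcripts depend on KLF2 in these cells, and the study's title places BMPER and the BMP effectors SMAD1 and SMAD5 downstream. All fold changes below are on the scale of log2(normalised reads + 1), siKLF2 minus siCtrl, with limma's adjusted p.

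KLF2 mRNA fell in every siKLF2 library, from 59.5 ± 3.85 normalised reads in siCtrl to 3.98 ± 1.02 in siKLF2 (SD, n = 4 each), a log2 fold change of -3.62 ± 0.21 (SE, adjusted p = 7.09e-07). BMPER, a secreted protein that binds BMPs and can inhibit or promote their signalling, fell with it, from 689 ± 120 to 262 ± 53.8 normalised reads (SD, n = 4 each), a log2 fold change of -1.40 ± 0.17 (SE, adjusted p = 0.000103). The lowest siCtrl library held 597 BMPER reads and the highest siKLF2 library 317. KLF2 (ENSG00000127528) lies on chromosome 19 at 16324817 to 16327874 and BMPER (ENSG00000164619) on chromosome 7 at 33904308 to 34156356, both on the plus strand of GRCh38. The siKLF2 libraries held so few KLF2 reads that its fold change moved with the pseudocount, reaching -2.85 with 5 added to each value, and was -3.88 in a count model.

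**Figure D1:**
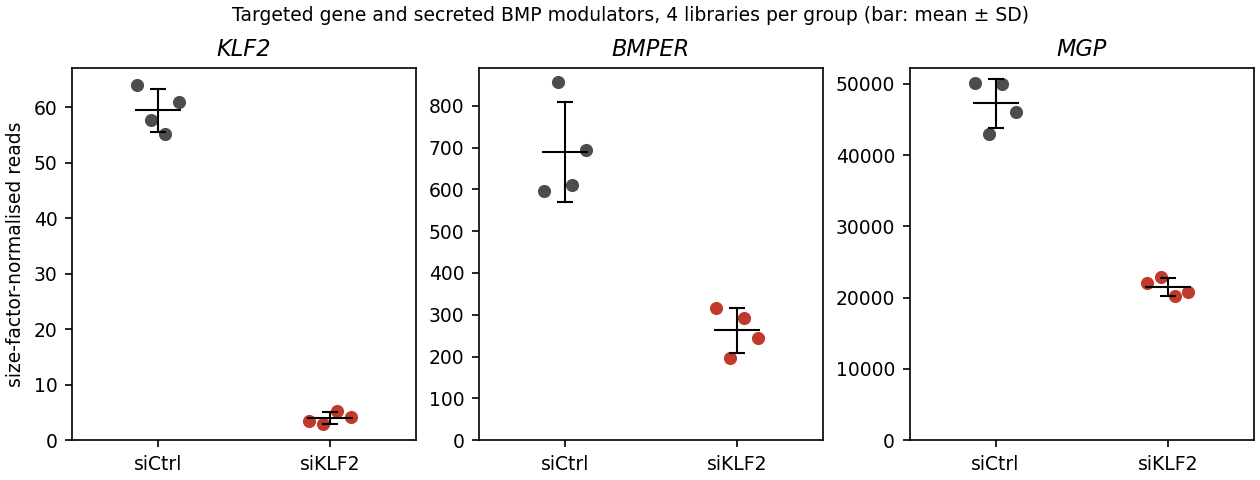
Normalised reads per library (y axis, from 0) of KLF2, BMPER and MGP in siCtrl and siKLF2; each point is 1 of 4 libraries per group and the bars give mean ± SD. For all 3 genes the siKLF2 libraries lie below every siCtrl library, with KLF2 at 3.98 against 59.5 and BMPER at 262 against 689 on average.

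A large part of the transcriptome differed between siKLF2 and siCtrl. Of 14678 genes tested, 3574 rose and 3352 fell, and 836 of the former and 626 of the latter changed at least 2-fold. With upper-quartile scaling in a count model the split was 2980 against 4247. Of the 6926 genes called by limma, 4819 kept their call and direction when a trend on GC content and length was removed. That trend, described below, varied with group, so not every call can be credited to the knockdown. Among protein-coding genes with a mean of at least 5 CPM and no overlap between the groups, the largest rises were in ADAM28, a membrane metalloprotease (5.96), MSR1, a scavenger receptor (4.44), SPON1 (4.37), CD69, an activation marker of lymphocytes (4.37), IL1A, the cytokine interleukin 1 alpha (4.30), CPA3, a carboxypeptidase of mast cells (4.22), the chemokine CXCL5 (4.10), FAT3 (4.07), HDAC9 (4.01), UNC5C (3.83), GBP5 (3.78) and the chemokine CXCL1 (3.70). IL1A went from 15.1 ± 3.28 to 313 ± 26 normalised reads and CXCL1 from 167 ± 11.5 to 2219 ± 471 (SD, n = 4 each).

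By the same rule, the largest falls were in the water channel AQP1 (-4.78), the oestrogen sulfotransferase SULT1E1 (-3.62), LIMS2 (-3.26), CRTAC1 (-2.93), the secreted chaperone CLU (-2.59), the gap junction genes GJA4 (-2.46) and GJA5 (-2.39), MATN2 (-2.41), PKNOX2 (-2.41), the proteoglycan BGN (-2.35), the laminin chain LAMA3 (-2.35) and the keratin KRT7 (-2.33). AQP1 went from 2047 ± 268 to 75.1 ± 20 normalised reads, and CLU, far more abundant, from 30419 ± 4184 to 5053 ± 746 (SD, n = 4 each). Adjusted p was at most 0.000164 for each of these 12 genes, and the rule itself required that no siKLF2 library overlapped with a siCtrl library. Over all tested genes 42.3% showed no overlap between the groups, where chance gives 2.86%.

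Genes known to be repressed by KLF2 rose together: 10 of 12 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 2.57e-06, adjusted p = 0.126 with an estimated correlation). They included the chemokine CXCL8 (3.67), the leukocyte adhesion receptor SELE (2.59), the VEGF receptor KDR (1.74) and the vessel-destabilising ligand ANGPT2 (1.70). ACE, the angiotensin-converting enzyme, was the member that fell (-1.90), and ADM had a log2 fold change of 0.22 (adjusted p = 0.0898), which passed the test at 0.76 once the trend on GC content described below was removed. Genes known to be induced by KLF2 split: 6 of 12 fell and 3 rose (also 6 and 3 adjusted over the list alone; camera adjusted p = 0.228). Camera called the list lower without the low-count filter (adjusted p from 0.000556 to 0.398 over the alternatives). GJA4 (-2.46), the prostaglandin transporter SLCO2A1 (-1.87), the haem-degrading enzyme HMOX1 (-1.67) and the nitric oxide synthase NOS3 (-1.36) fell, while the anticoagulant receptor THBD (0.97) and the complement regulator CD55 (1.10) rose. With the GC trend removed, HMOX1 stood at -1.08 and NOS3 at -0.88. Of 14 KLF family genes 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.817), and besides KLF2 itself KLF4 (-1.46), KLF15 (-1.10, or -0.60 after GC correction) and KLF8 (-0.94) fell. In the kinase pathway from MEKK3 to MEF2 factors that lies upstream of KLF2, 3 of 7 genes rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.817). MAP3K3 (-0.85) and MAP2K5 (-0.53) fell, and MEF2A rose (0.53). After GC correction MEF2A stood at 0.20, and 1 of the 7 rose and 2 fell.

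Among extracellular BMP modulators, 2 of 8 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.993). Besides BMPER, the matrix protein MGP fell (-1.14 ± 0.08, SE, adjusted p = 1.92e-06), from 47249 ± 3403 to 21465 ± 1230 normalised reads (SD, n = 4 each). CRIM1 rose (1.01) and so did FSTL1 (0.20, adjusted p = 0.0364), whose adjusted p ran from 0.0136 to 0.205 over the alternatives, several of which ended its call. FST (0.13), FSTL3 (0.27), TWSG1 (0.29) and NBL1 (-0.58) did not pass the test. FSTL3 did so after GC correction (0.89), where TWSG1 stood at 0.02 and NBL1 at 0.01, and TWSG1 without siCtrl 2 (0.39). Of 17 BMP ligands, receptors and SMADs, 7 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.539), and 5 rose and 4 fell after GC correction. BMP4 fell (-1.22), while BMP2 (0.36), the co-receptor RGMB (0.64) and GDF15 (0.94, or 1.61 after GC correction) rose. GDF15 is also in the list of p53 target genes, so its rise is not particular to the BMP list. BMP6, the most abundant member outside the calls, had a log2 fold change of 0.01 (adjusted p = 0.956), and passed the test at 0.31 after GC correction. SMAD5 rose as deposited (0.54, adjusted p = 0.0134), but its siCtrl 3 value is the only value in the table that is not a whole number of reads. Without that library it stood at 0.68 (adjusted p = 0.00121, 3 siCtrl libraries), and after GC correction at 0.26 (adjusted p = 0.224; 0.000259 to 0.224 over the alternatives).

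Target genes of SMAD1/5 did not move in a common direction: 5 of 15 rose, 3 fell and 7 did not pass the test (5 and 3 adjusted over the list alone; camera adjusted p = 0.817). After GC correction 9 rose and 3 fell. The Notch effectors HEY1 (1.30) and HEY2 (1.46), the Notch ligand JAG1 (1.23), ID2 (0.66) and the netrin receptor UNC5B (0.91) rose. UNC5B did so with adjusted p = 0.0215, which became 0.0558 without siCtrl 1 and 0.0568 without siKLF2 1 (0.00177 to 0.0619 over the alternatives). The replicate number as a block and DESeq2 also ended the UNC5B call. TMEM100 (-1.39), BAMBI (-1.24) and the inhibitory SMAD7 (-0.74, or -0.44 after GC correction) fell. ID1, a direct and widely used readout of BMP signalling, went from 309 ± 16 to 270 ± 52 normalised reads (SD, n = 4 each), a log2 fold change of -0.21 ± 0.13 (SE, adjusted p = 0.214), and ID3 likewise stood at -0.21 (adjusted p = 0.314). Without siKLF2 1, ID1 passed the test as lower (-0.33). Both turned positive once the trend on GC content was removed, ID1 to 0.36 (adjusted p = 0.0257, the alternatives ranging from 0.0257 to 0.472) and ID3 to 0.32 (adjusted p = 0.00589, the alternatives ranging from 0.00589 to 0.997).

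**Figure D2:**
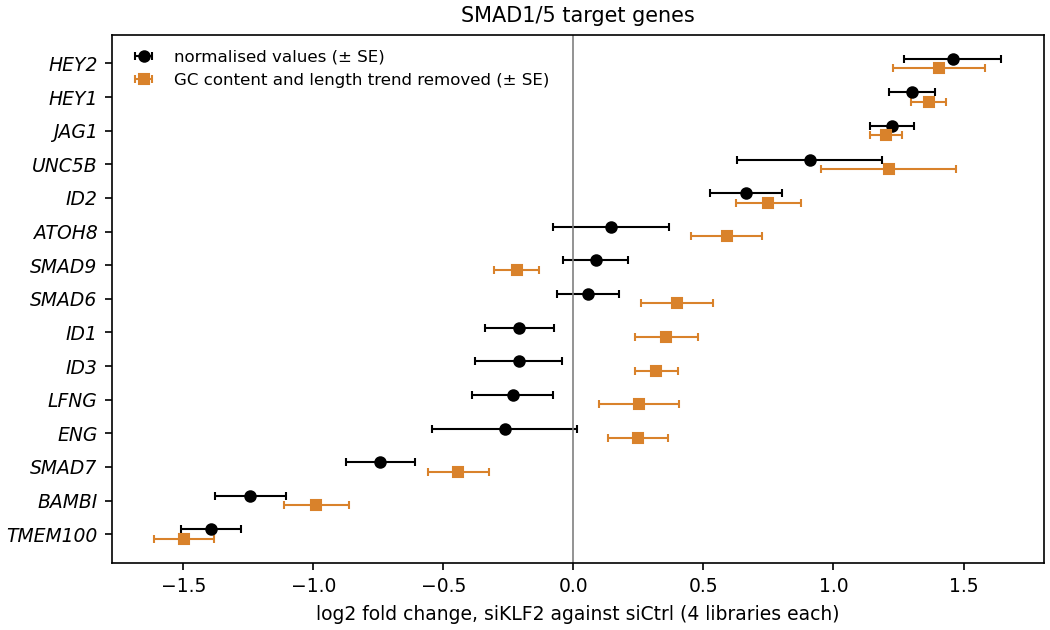
Log2 fold change (x axis, siKLF2 against siCtrl, 4 libraries each, bars ± SE) of the 15 tested SMAD1/5 target genes, from normalised values (circles) and with the trend on GC content and length removed (squares). HEY1, HEY2 and JAG1 lie above 1 and TMEM100 below -1 in both, while ID1 and ID3 lie on opposite sides of 0.

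Inflammatory genes of the NF-kB pathway rose: 12 of 19 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 6.79e-06, adjusted p = 0.144 with an estimated correlation). IL1A, CXCL1, CXCL8 and SELE led the list, whereas NFKB1 itself had a log2 fold change of 0.08 (adjusted p = 0.377). Interferon-stimulated genes did not follow: 2 of 26 rose and 10 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.0984). The list was called lower without siCtrl 4, without siKLF2 1, without both libraries of steepest GC slope, without the low-count filter and with the replicate number as a block (adjusted p from 0.0084 to 0.932 over the alternatives). The risers were the chemokines CXCL10 (3.29) and CXCL11 (2.52). IFITM1 (-1.33) and the antiviral GTPase MX1 (-0.51) fell, and IFI44L stood at -0.06 (adjusted p = 0.812). After GC correction IFITM1 stood at -0.82, MX1 lost its call (-0.32), IFI44L passed the test as lower (-0.55), and 2 of the 26 rose and 7 fell. IFITM1 lost its call without the low-count filter (-1.3; adjusted p from 0.000558 to 0.0771 over the alternatives).

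Angiogenic and tip cell genes, those of sprouting endothelium, also rose: 15 of 23 rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 9.96e-05, adjusted p = 0.126 with an estimated correlation). The tip cell marker ESM1 rose from 1793 ± 218 to 18535 ± 1005 normalised reads (SD, n = 4 each), a log2 fold change of 3.38, and the chemokine receptor CXCR4 (2.70), the collagenase MMP1 (2.49) and the basement membrane protein NID2 (2.47) rose with it. MMP2 did not pass the test (-0.32, adjusted p = 0.163).

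Genes of TGF-beta signalling and mesenchymal cells rose as a list: 15 of 23 rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.0041, adjusted p = 0.126 with an estimated correlation). The transcription factor SNAI2 (2.16), TGFBI (1.99), the cadherin CDH2 (1.13) and the collagen COL3A1 (1.06) rose, and fibronectin (FN1) was at 348670 normalised reads in siKLF2 against 347681 in siCtrl (log2 fold change 0.00, adjusted p = 0.966). YAP/TAZ target genes rose in 12 of 21 cases and fell in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.126 with an estimated correlation), among them tissue factor F3 (2.80), ANKRD1 (1.18) and CYR61 (0.92). All 3 smooth muscle markers abundant enough to test, of 8, rose (3 adjusted over the list alone; camera adjusted p = 0.0694), ACTA2 by 1.28, SYNPO2 by 0.93 and TAGLN by 0.79 (0.52 and 1.22 for the latter pair after GC correction). Of 7 fibroblast markers 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.228): LUM (2.51), PDGFRA (1.08) and COL3A1 rose, PDGFRB fell (-2.33), and COL1A1 stayed at 25.1 ± 13.4 and 27.1 ± 7.06 normalised reads (SD, n = 4 each, adjusted p = 0.627). Basement membrane and matrix genes went both ways, with 7 of 20 up and 6 down (8 and 6 adjusted over the list alone; camera adjusted p = 0.859). COL4A1 rose from 17510 ± 1282 to 59287 ± 10036 normalised reads (SD, n = 4 each), and elastin (ELN) fell from 112 ± 22.6 to 2.75 ± 1.19 (SD, n = 4 each).

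p53 target genes rose: 10 of 14 rose and the other 4 did not pass the test (also 10 rose adjusted over the list alone; camera adjusted p = 0.000166, adjusted p = 0.126 with an estimated correlation). The death receptor FAS (1.61), MDM2 (1.34, or 0.83 after GC correction), ZMAT3 (1.33) and TNFRSF10B (0.72) were among them, and BTG2 stood at -0.12 (adjusted p = 0.186), passing the test as lower with upper-quartile scaling (-0.21). Cell cycle genes were the list called lower: 21 of 28 fell and 1 rose, or 23 and 3 after GC correction (22 and 2 adjusted over the list alone; camera adjusted p = 3.42e-05, adjusted p = 0.379 with an estimated correlation). The proliferation marker MKI67 fell from 3788 ± 124 to 2519 ± 50 normalised reads (SD, n = 4 each, log2 fold change -0.59), CDC20 (-1.63) and HMGB2 (-0.78) fell, and CCNE2 was the member that rose (0.94, or 0.61 after GC correction).

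**Figure D3:**
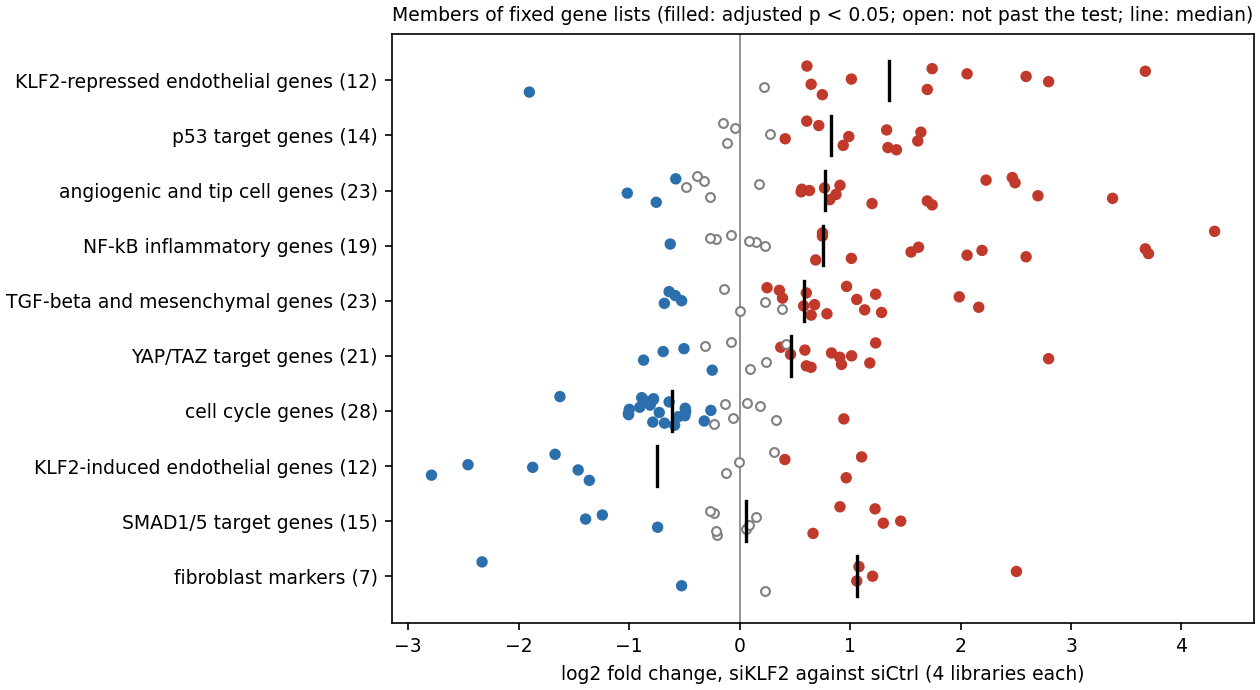
Log2 fold change (x axis, siKLF2 against siCtrl, 4 libraries each) of each tested member of 10 gene lists, with the number of tested members in parentheses; filled points have adjusted p below 0.05, open points do not, and lines mark medians. The medians run from 1.36 in genes repressed by KLF2 to -0.61 in cell cycle genes among the 7 called lists, and the members of the lower 3 lists lie on both sides of 0.

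Camera called none of the lists of glycolysis, cholesterol and stress response genes with normalised values. Of 19 glycolysis genes 2 rose and 9 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.0984), or 3 and 5 after GC correction, with SLC2A3 (0.72) and PFKFB3 (0.61, or 1.02 after GC correction) up and LDHA (-0.53) down. Camera called glycolysis genes lower without the low-count filter (adjusted p from 0.0158 to 0.932 over the alternatives). Of 17 genes of cholesterol synthesis and uptake 5 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.974), SC5D by 1.14. Of 14 genes of the integrated stress and unfolded protein response 2 rose and 4 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.57), with ATF4 at -0.91 (-0.53 after GC correction) and ATF3 at 0.97. After GC correction 5 rose and 3 fell, and the direction of the list turned from lower to higher, again without a call.

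Camera called none of the lists of pan-endothelial, junction, arterial, venous, coagulation and vasoactive genes with normalised values. Of 16 pan-endothelial genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.45), or 4 and 5 after GC correction. CDH5, the cadherin of endothelial junctions, stood at 0.27 (adjusted p = 0.0566), PECAM1 rose (0.31), and MMRN2 (-0.83) and SOX18 (-0.83) fell. After GC correction PECAM1 and SOX18 lost their calls (0.11 and -0.06), MMRN2 stood at -0.50 and CDH5 passed the test as higher (0.50). CDH5 also did so without siCtrl 3 (0.32), without siKLF2 4 (0.35), without both (0.40) and without the low-count filter (0.27; adjusted p from 7.6e-06 to 0.213 over the alternatives). Junction and barrier genes included 4 of 17 that rose and 2 that fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.751), JAM2 by 1.47, and after GC correction 5 rose and 5 fell. Of 22 arterial and Notch genes 11 rose and 7 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.45), SEMA3G (2.57) and CXCR4 rising and GJA5 falling. Of 9 venous and capillary genes 3 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.817), RGCC by 2.33, with SELP (-1.52) and PLVAP (-1.51) lower. Coagulation and fibrinolysis genes rose in 8 of 15 cases and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0984), or 7 and 4 after GC correction: F3 and the inhibitor TFPI2 (1.41) rose and the protein C receptor PROCR fell (-0.85, or -0.54 after GC correction). Camera called this list higher without the low-count filter and without both libraries of steepest GC slope (adjusted p from 3.69e-05 to 0.567 over the alternatives). Vasoactive genes were divided, with 5 of 16 up and 6 down (5 and 6 adjusted over the list alone; camera adjusted p = 0.817), or 7 and 4 after GC correction: the vasoconstrictor EDN1 (0.75) and the cyclooxygenase PTGS2 (1.61) rose, and NOS3 and ACE fell.

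Of 4 tested lymphatic endothelial markers 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.346), LYVE1 by 1.23, while PROX1, which specifies lymphatic identity, stood at 0.13 (adjusted p = 0.69). Only 2 of 10 leukocyte markers and 2 of 7 epithelial markers were abundant enough to test, too few for a list test. LAPTM5 rose (1.08) and CD74 fell (-0.99), and KRT19 (-3.62) and EPCAM (-0.97) fell (1 up and 1 down, and 2 down, also adjusted over the list alone). CD74 lost its call after GC correction (-0.42), and EPCAM with DESeq2 (-0.98). Of 13 mitochondrially encoded genes 2 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.993).

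The libraries of the groups also differed in composition. The 10 most abundant genes of each library took 7.83% ± 0.175 of reads in siCtrl and 7.41% ± 0.179 in siKLF2 (SD, n = 4 each, exact two-sided permutation test, p = 0.0286). Ribosomal protein genes took 4.15% ± 0.48 of reads in siCtrl and 2.5% ± 0.26 in siKLF2 (SD, n = 4 each; exact two-sided permutation test, p = 0.0286, the smallest this design allows). Log2 deviations from the mean of all 8 libraries rose with transcript GC content in siCtrl, by 0.21 ± 0.19 per 10 points of GC. They fell in siKLF2, by -0.21 ± 0.22 (SD, n = 4 each, exact two-sided permutation test, p = 0.0286). These group means are opposite by construction, so only their difference, 0.418, is informative. Which group departs cannot be told from it. The gradient was steepest in siCtrl 3 (0.46) and siKLF2 4 (-0.52). Across protein-coding genes the median log2 fold change went from 0.34 in the fifth of lowest GC content to -0.52 in the fifth of highest; genes are not independent replicates. With the gradient removed from each library, 3666 genes rose and 3567 fell, and 4819 of the 6926 calls were shared in the same direction. All 7 called lists were still called, and smooth muscle markers joined them. Mitochondrial reads were 4.18% ± 0.3 and 3.9% ± 0.31 (SD, n = 4 each; exact two-sided permutation p = 0.229).

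**Figure D4:**
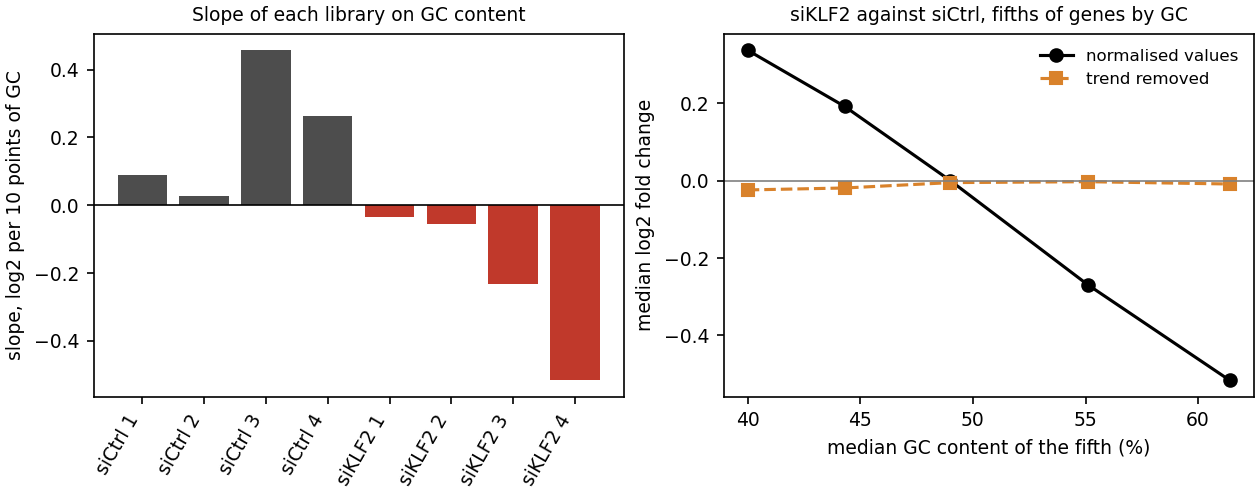
Left, slope of each library's log2 deviation from the mean of all 8 libraries on transcript GC content (y axis, log2 per 10 points), siCtrl in grey and siKLF2 in red. Right, median log2 fold change (y axis) in 5 equal groups of protein-coding genes ordered by GC content (x axis, median of the group), before and after the trend was removed; the former runs from 0.34 to -0.52.

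The list calls rest on camera's preset correlation: with the correlation estimated from these 8 libraries camera called 0 of 28 lists, and 6 lists, all higher, had an unadjusted p below 0.05, while the rotation test fry, which does not compare a list with other genes, called 12 higher and 3 lower. These were the 7 lists called by camera and 8 more: arterial and Notch, junction and barrier, coagulation, fibroblast, smooth muscle and lymphatic genes (higher), and the KLF family and genes induced by KLF2 (lower). The KLF family list includes KLF2, the target of the siRNA, whose fall (-3.62) enters its mean and its tests. Its lower direction is therefore in part fixed by the knockdown. After GC correction camera with an estimated correlation called 4 lists, all higher: genes repressed by KLF2, TGF-beta and mesenchymal, NF-kB, and angiogenic and tip cell genes (adjusted p = 0.0412 for each, 3.22e-11 to 0.144 over their alternatives). The median had the opposite sign to both the mean and the test for the KLF family, BMP modulators, junction genes and cholesterol genes. The mean differed in sign from the other values for basement membrane genes, and the test did for mitochondrially encoded genes; camera called none of these lists. Its direction reversed with GC correction, without a call, for BMP modulators, stress response, basement membrane and mitochondrially encoded genes.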

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

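The comparisons with other splits of the libraries were fixed before their results were seen; the tests on GC content, on the called lists and on other cells were chosen after.

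None of the 34 other splits of the 8 libraries, 4 against 4, called a gene with limma, against 3574 higher and 3352 lower for the real split (1 of 35 splits for each). At an unadjusted p below 0.05 the real split had 8159 genes and the highest other 4206. Chance assignment is excluded for both counts only at this share, 1 of 35, the smallest the design allows. Each other split mixed the groups, so their difference added to the spread within its sides. The comparison does not address anything else that varies with group, such as the GC gradient. Chance assignment is not excluded for the lists: 8 of the 35 splits, the real one included, called at least the 7 lists of the real split, and the highest other called 10. All 7 of those other splits kept 3 libraries of a group together, and so part of the group difference; the 18 splits with 2 libraries of each group on a side called at most 4.

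Fold changes fell with GC content. That libraries differ in how well GC-rich transcripts were recovered has the values it needs: slopes ranged over 0.43 within siCtrl and 0.482 within siKLF2, at least 1.03 times the 0.418 between the group means. An effect of the knockdown on GC-rich genes cannot be told apart from it, because the slopes of the groups did not overlap (gap 0.0605 log2 per 10 points), so group and gradient vary together. Against the trend as the whole source of the list calls, all 7 of 7 lists were called in the same direction once it was removed. This carries limited weight, because several mixed splits called as many lists after removal. With siCtrl 1, 2 and 3 and siKLF2 2 or siKLF2 4 on a side, 8 lists were called, as in the real split. The same number was called with siCtrl 1, 2 and 4 and siKLF2 1 or siKLF2 3 on a side. Other mixed splits called 7, such as siCtrl 1, 2 and 3 with siKLF2 1. All of these splits keep most of a group together. Genes of extreme GC content with small fold changes, ID1 and ID3 among them, may owe their sign to the GC trend.

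Fibroblast and smooth muscle markers rose in part. More fibroblasts or mural cells in the siKLF2 cultures would bring reads of the markers that they express, which need not be all 10 tested. Of the 10, 7 gained more than 2 SE, COL3A1 by 3220 ± 265 normalised reads, LUM by 157 ± 8.23 and DCN by 35.7 ± 3.8 (SE). COL1A1 gained 2.05 ± 7.59, while COL1A2 changed by -275 ± 39.3 and PDGFRB by -44.2 ± 5.02 (SE), losses that added cells alone would not give. The markers thus went both ways, and 5 of the 10 are also in another list. Whether such cells account for the rises cannot be told apart from a change within the endothelial cells or selection within the cultures, because no profile of the added cells was measured here.

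Among 336 groups of 4 libraries tested (named genes and library measures), 11 had a library far from the other 3, where chance gives about 1 in 20. The gap divided by the group's range was 0.972 for SPON1 in siKLF2 (siKLF2 3 at 238 normalised reads, the others 177 to 179), 0.967 for UNC5B in siKLF2 (siKLF2 1, 26.9 against 15.7 to 16.0) and 0.963 for PROX1 in siKLF2 (siKLF2 2, 97.9 against 135 to 137). It was 0.918 for FST (siCtrl 1), 0.915 for CDH2 (siCtrl 3), 0.912 for HEY1 (siCtrl 1), 0.9 for HERPUD1 (siCtrl 2), 0.882 for CD55 (siCtrl 1), 0.87 for TFPI2 (siCtrl 1) and 0.869 for RELN (siCtrl 3) within siCtrl, and 0.88 for ELN in siKLF2 (siKLF2 2).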

How the results depend on the processing

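Alternatives on TMM, pseudocounts, GC content (alone or with an estimated correlation) and the steepest libraries were chosen after seeing the data; the rest were planned. KLF2 and BMPER stayed lower and past the threshold in every alternative run, KLF2 from -3.96 (upper-quartile factors) to -2.85 (pseudocount 5) and BMPER from -1.57 to -1.27. Leaving out 1 library gave 2812 to 3846 genes higher and 2291 to 3445 lower. At adjusted p below 0.01 the counts were 2278 and 1657, and at 2-fold or more 836 and 626, fewer by construction. The values gave no sign that replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at -0.3, -0.49, -0.11 and -0.25, and no siCtrl library correlated best with its own number. The GC gradient was not removed from these deviations and could hide a pairing, which the labels leave open. With the replicate block 2657 genes were higher, 2115 lower, 6 lists higher and 2 lower.

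Lists called lower numbered 4 without the low-count filter and 2 without both libraries of steepest GC slope, and 1 to 2 with each library left out (interferon-stimulated genes were called without the filter, without both steepest libraries, with the block, and without siCtrl 4 or siKLF2 1; adjusted p from 0.0084 to 0.932 over the alternatives). Smooth muscle markers were called without siCtrl 3, siKLF2 4 or both, with GC correction and with fry (adjusted p from 0.000794 to 0.28 over the alternatives). Lists called were 0 higher and 0 lower with an estimated correlation, 4 and 0 with it after GC correction, and 12 and 3 with fry. Without both steepest libraries 3022 genes were higher and 2626 lower. Of the 162 named genes, ID1 (0.36), ID3 (0.32) and MMRN1 (-0.37, from 0.08) changed sign and gained a call with GC correction, where 10 others gained a call in the same direction and 7 lost one; genes without a call in either fit, NBL1 among them, also changed sign. No other alternative changed the sign of a named gene with a call in either fit. Beyond the GC trend the cause was not tested. Genes with few reads in a group, KLF2 in siKLF2 and RELN in siCtrl among them, have fold changes limited by depth.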

Other observations

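The interferon-stimulated gene IFI44L was abundant in both groups, with means of 2180 CPM in siCtrl and 1950 in siKLF2, ranks 25 and 33 among all genes.

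SMAD5, named in the study's title, stands apart in the table in a pair of ways. Its value in siCtrl 3, 1717.8 normalised reads, corresponds to 1713.5 reads and is the only 1 of 259368 values that is not a whole number of reads (tolerance 1e-06). The statistic in the authors' deposited table, 4.28, is not the ratio of its log2 fold change to its standard error, 2.86, in this row alone of 32421. The other siCtrl libraries held 1036, 1515 and 1202 reads.

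A hypothesis, tested after its values were seen, is that the GC trend hides a common rise of SMAD1/5 target genes after KLF2 knockdown. With the trend removed, 9 of 15 members rose, the median log2 fold change moved from 0.05 to 0.36, and camera gave adjusted p = 0.11 (0.11 to 0.997 over the alternatives). But 3 members, TMEM100 (-1.50), BAMBI (-0.99) and SMAD7 (-0.44), were still called lower, which argues against a rise common to all. These 3 do not weigh against a shift of the list, since of all 14635 genes 3666 rose and 3567 fell after removal. That ID1, ID3, SMAD6 and ATOH8 rise may hold for part of the list; with normalised values of all 8 libraries none of these 4 passed the test, and without siKLF2 1 ID1 passed it as lower (-0.33). Libraries without a GC gradient between groups, or quantitative PCR of ID1 and ID3, could decide it.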
